A study of Homo sapiens with 8 samples.

How the data were processed

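Gene expression was measured in 4 cell lines of clear cell renal cell carcinoma, SKRC59, SKRC52, SKRC1 and SKRC10, on 8 Agilent 2-colour arrays. Per the labels, each array paired RNA of mock-treated cells (PBS) in the Cy3 channel with RNA of drug-treated cells of the same line in the Cy5 channel. 4 arrays hold AZA, labelled as a DNA methylation inhibitor, at 5 µM for 96 h, and 4 hold TSA, a histone deacetylase inhibitor, at 300 nM for 18 h, with 1 array per line and drug. The mock cells were kept for the same time as the treated cells, so the mock RNAs of the AZA and TSA arrays differ. Dyes were not swapped. A dye effect of a probe can therefore not be told from a drug effect in either comparison with mock, whereas a constant dye effect cancels in the difference between the drugs. Dose and time differ between the drugs, so drug, dose and time cannot be separated. Slide A holds SKRC59 and SKRC52 and slide B holds SKRC1 and SKRC10, with both drugs on each slide. For 1 AZA array, the title names SKRC52, while the source name and the cell line field give SKRC592, which could also stand for SKRC59. It was taken as SKRC52 by its title, and the pairing by line and the values of single lines rest on this. The 4 lines are the replicates. Each p-value rests on the spread between these lines, pooled over both drugs. The main fit takes both arrays of a line as independent, so the difference between the drugs is tested without the pairing.

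Per the file headers, the arrays (design 014850) were read with Agilent Feature Extraction 9.1.3.1, which gives each spot a mean intensity and a local background intensity in each channel. Per the file headers, the same software also deposited LogRatio, the log10 ratio of its background-subtracted and dye-normalized Cy5 signal over that of Cy3. A deposited table of values holds the authors' log2 ratios of the same arrays. Set against the scanner values, each of its columns was a treated over mock ratio on the log2 scale and correlated at 0.9979 to 0.9991 across probes with loess-normalized ratios made without background correction. Its columns are centred near 0, with medians of 0.0126 to 0.0192. The submitters' processing notes name limma; the steps and the version are not given in the sources used here.

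The ratios reported here were computed from the scanner intensities with limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8). Background was corrected with normexp (offset 50) on all spots, and each array was normalized by loess with its 1639 control spots at weight 0. Spots with an outlier mark were set to missing, saturated spots were kept, and no normalization between arrays was applied. The 43376 remaining spots were averaged to 41000 probes, of which 37833 were well above background in either channel on at least 2 of the 8 arrays. Accessions and symbols of the array design were matched to current symbols through a RefSeq gene table of assembly GRCh38.p14, which was used for names and for which genes lie together on a chromosome. Of the 41000 probes, 23434 were named by accession, 2317 by symbol and 1043 by an older symbol, and 14206 kept the name in the file. The files name no genome build, so no coordinates are given. A gene stands for its probe with the highest mean signal over all arrays, which gave 28524 features, 16832 with a current symbol. Among called genes with several probes, the mean of the other probes had the opposite sign for 155 of 1295 genes with AZA and for 204 of 2887 with TSA.

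Each comparison was fitted with lmFit and eBayes on log2(treated/mock) over all 8 arrays, with 1 mean per drug and a shared estimate of the spread (6 residual and 2.11 prior degrees of freedom). A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over all features of a comparison. Values are given as mean ± SD of the log2 ratio over the 4 lines, or as the fold of that mean. Where the mock channel was not well above background on any of the 4 arrays, the fold is a lower bound. It sets the mean treated signal against, per array, the higher of the lowest signal among probes well above background and the probe's own, with each channel taken after loess and Aquantile, and it remains open to dye bias. 27 gene lists with 1032 members, 990 of them measured, were tested with camera at a preset correlation of 0.01 between genes. Camera was repeated with an estimated correlation, and list p-values were adjusted over the 27 lists of a comparison. The lists, tests, thresholds and naming rule were set before the data were examined, except where the text says otherwise.

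Genes are named by this rule: for each drug, the 10 highest and 10 lowest mean ratios among called genes with the same sign in all 4 lines; for the difference between the drugs, the 5 highest and 5 lowest; up to 4 members of each list with the smallest p; and always DNMT1, CDKN1A, GREM1, NEURL1, LAD1, NEFH, SFRP1, RASSF1, CDH1, VHL and CA9. Some genes that the rule selects are left out of the text. Features raised with AZA alone were counted in each line as at least 2-fold higher with AZA, under 1.4-fold higher with TSA and not well above background in the mock channel of the AZA array. Their number in several lines was set against 1000 permutations within each line, among features with the same lines near background in the mock channel, a test chosen after seeing the data.

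The samples are paired by cell line. A line's AZA and TSA ratios deviated together from the means of the drugs, with correlations across genes of 0.416, 0.309, 0.278 and 0.449 in SKRC59, SKRC52, SKRC1 and SKRC10, against -0.249 to 0.016 between different lines, which centring on the means draws below 0. The alternative with cell line as a block used duplicateCorrelation (0.3) for each drug and line as a fixed term for the difference, with cameraPR on its z values for the lists. No arrays were duplicates of each other: the highest correlation of any pair was 0.765.

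Other background corrections, normalizations, filters, probe rules, variance priors, array weights, the slide, each line left out and the authors' value table were tried as alternatives. On simulated data with 28524 features and the spread of these arrays, the AZA comparison recovered 49.3% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 100% of those changed 4-fold. The TSA comparison recovered 46.3%, 76.1% and 100%. For the difference between the drugs the shares were 7.5%, 49.3% and 95.5% for genes changed with AZA, and 1.5%, 46.3% and 97% for genes changed with TSA. The simulation changed 66 or 67 features at each fold, with noise independent between arrays. It leaves out the pairing by line and has far fewer changed features than were called here. The shares are therefore not the power of these comparisons. The number of arrays limits the precision.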

Results

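The data comprised 8 arrays, 4 for each drug, with 1 array per cell line and drug. Across the arrays the median spot intensity was 228 to 273 in the mock channel and 368 to 506 in the treated channel. The share of spots well above background was 72.7% to 81.8% in the mock channel and 78.9% to 91.8% in the treated channel. In single arrays, 1074 to 1678 features were at least 2-fold higher with AZA and 302 to 810 at least 2-fold lower, and with TSA 1411 to 2227 were higher and 1569 to 1814 lower. The series title names functional markers of CpG island methylation, so the first question was which genes changed with the methylation inhibitor AZA, and the second which changed with TSA.

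After AZA, the cancer-testis and germline list, of genes normally active in testis, had the highest mean of the 27 lists (1.36), although p53 targets had a higher median (0.90 against 0.81) and most cancer-testis genes were not called. Of 87 measured members 38 rose and 0 fell (50 and 0 adjusted over the list alone). The list mean was above 0 in every line, at 1.35 in SKRC59, 2.22 in SKRC52, 0.73 in SKRC1 and 1.14 in SKRC10. It was 1.79 on slide A and 0.94 on slide B. Camera gave adjusted p = 1.13e-14, and adjusted p = 0.37 with an estimated correlation. PAGE5 rose 25.3-fold (log2 4.66 ± 0.75, mean ± SD, n = 4 lines here and below), GCNA, a germ cell nuclear protein gene, 23.5-fold (4.56 ± 1.21), FMR1NB 20.4-fold (4.35 ± 0.81) and PAGE2 17.7-fold (4.15 ± 0.88). TKTL1, a transketolase-like gene, rose 23.4-fold (4.55 ± 1.32). The meiotic gene SYCP3 rose 14.4-fold (3.84 ± 0.54), XAGE3 11.4-fold (3.52 ± 0.73) and MAEL, which acts in germ cell transposon silencing, 10.1-fold (3.34 ± 0.41). The adjusted p of these 8 genes was 5.56e-05 to 0.0011. SPANXA1 (4.91 ± 3.06), VCX3A (4.57 ± 2.81), VCX (4.47 ± 2.70), VCX2 (4.46 ± 2.72) and SPANXB1 (4.00 ± 2.25) also rose, with adjusted p of 0.0104 to 0.0331, but their log2 ratio was only 0.53 to 0.79 in SKRC1. PAGE, SPANX and VCX genes have near-identical copies, so their probes cannot be assigned to single copies. Another probe had a mean of 3.34 for SPANXA1 and of 1.71 for VCX2.

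The SPANX and VCX ratios were high in 3 lines and low in SKRC1. Without SKRC1 the log2 means were 6.37 for SPANXA1, 5.90 for VCX3A, 5.74 for VCX, 5.74 for VCX2 and 5.07 for SPANXB1, and without SKRC52 they were 4.22, 3.73, 3.67, 3.64 and 3.53. All 5 of these calls were lost without SKRC59 (adjusted p 0.0688 to 0.158, with means of 4.86, 4.17, 4.03, 4.04 and 3.97) and without SKRC52 (0.0616 to 0.0796), and all except SPANXB1 without SKRC10 (0.0624 to 0.0886), where SPANXA1 had a mean of 4.18. Mock signal was well above background on 3 of 4 arrays for FMR1NB, XAGE3, SPANXB1, VCX, VCX2 and VCX3A and on 2 of 4 for SYCP3.

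Lists of interferon, p53, cytokine and deacetylase inhibitor response genes were also higher after AZA. Of 56 interferon-stimulated genes 19 rose and 0 fell (26 and 1 adjusted over the list alone; adjusted p = 7.86e-07, and adjusted p = 0.382 with an estimated correlation). The sensors of viral RNA IFIH1 and RIGI rose 2.99-fold (1.58 ± 0.33) and 2.86-fold (1.52 ± 0.45), the ubiquitin-like ISG15 3.94-fold (1.98 ± 0.37) and the transcription factor IRF9 2.08-fold (1.05 ± 0.38). Of 32 p53 targets 16 rose and 0 fell (23 and 2 adjusted over the list alone; adjusted p = 2.73e-06, and adjusted p = 0.399 with an estimated correlation). The death receptor gene FAS (1.88 ± 0.31), GADD45A (0.91 ± 0.11) and the cell cycle inhibitor CDKN1A (1.26 ± 0.57) were among them, with a mean of 1.96 for another CDKN1A probe. Of 36 inflammatory cytokine genes 8 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 0.000194, and adjusted p = 0.399 with an estimated correlation). CCL20 rose 12.9-fold (3.69 ± 1.19) and LTB 4.18-fold (2.06 ± 0.55). Of 32 genes reported to rise with histone deacetylase inhibitors, 11 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.000529, and adjusted p = 0.275 with an estimated correlation). DHRS2 (2.21 ± 1.06) and the polyamine enzyme gene SAT1 (2.15 ± 0.31) were among those that rose. On slides A and B the list means were 0.60 and 0.79 for interferon-stimulated genes, 0.97 and 0.68 for p53 targets, 1.28 and 0.34 for cytokines, and 0.76 and 0.52 for the deacetylase inhibitor genes. The mean of the p53 list was only 0.176 in SKRC1, against 0.802 in SKRC59, 1.137 in SKRC52 and 1.175 in SKRC10. The cytokine call was lost within slide B (adjusted p 0.0743). The CDKN1A call was lost without SKRC59 (0.118), SKRC52 (0.0967) or SKRC10 (0.0658), with means of 1.20, 1.13 and 1.17, and the GADD45A call without SKRC59 (0.0689), with a mean of 0.94.

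The epithelial, hypermethylated, imprinted and mesenchymal lists were higher after AZA, although most of their members were not called. Of 30 epithelial genes 12 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 0.000129, and adjusted p = 0.0886 with an estimated correlation). The keratin gene KRT7 (3.58 ± 1.18), the anchoring filament gene LAD1 (2.05 ± 0.67), the splicing regulator ESRP2 (1.54 ± 0.51), the adhesion gene CDH1 (1.85 ± 0.69) and the tight junction gene OCLN (1.19 ± 0.46) were among them. Of 64 genes reported as hypermethylated in renal cancer 15 rose and 0 fell (17 and 0 adjusted over the list alone; adjusted p = 6.04e-05, and adjusted p = 0.0886 with an estimated correlation). The epithelial and hypermethylated lists share 8 genes. CST6, a protease inhibitor gene, rose 12.5-fold (3.64 ± 0.37), the neurofilament gene NEFH 5.54-fold (2.47 ± 0.62) and the bone morphogenetic protein antagonist GREM1 at least 5.57-fold (adjusted p 0.000907). GREM1 was not well above background in the mock channel of any line and was above it in the treated channel of all 4. Of 34 imprinted genes 11 rose and 0 fell (11 and 1 adjusted over the list alone; adjusted p = 0.00257, and adjusted p = 0.37 with an estimated correlation). The growth factor gene IGF2 rose 5.19-fold (2.38 ± 0.95), the noncoding H19 3.18-fold (1.67 ± 0.52) and MEST 3.68-fold (1.88 ± 0.69). The other probe of IGF2 had a mean of 0.02 and that of H19 of 0.31, so these changes rest on single probes. Of 27 mesenchymal genes 8 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 0.00248, and adjusted p = 0.0886 with an estimated correlation). The collagen gene COL1A2 was one of them (2.17 ± 1.00, and 0.64 by another probe). The means on slides A and B were 0.80 and 0.79 for epithelial, 0.79 and 0.61 for hypermethylated, 0.42 and 0.47 for imprinted and 0.49 and 0.65 for mesenchymal genes.

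Several of these genes were near background in mock cells. Mock signal was well above background on 3 of 4 arrays for KRT7 and LAD1 and on 2 of 4 for CDH1, MEST and COL1A2. Whether any gene of the hypermethylated list was first reported from these cell lines is not given in the sources used here, so its count may not be independent evidence. Without SKRC59 the CDH1 call was lost (adjusted p 0.0734, mean 1.88). Of 63 ribosomal protein genes 23 rose and 6 fell (26 and 7 adjusted over the list alone; adjusted p = 0.00844, and adjusted p = 0.37 with an estimated correlation). The changes were small: RPS20 had a mean of 0.94 ± 0.13 and RPL3 of -0.80 ± 0.34. That list's call was lost with Agilent's own ratios (adjusted p 0.2) and within slide B (0.0684), and its mean was 0.16 on slide A and 0.14 on slide B.

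The cholesterol synthesis and proliferation lists were lower after AZA, although most of their members were not called. Of 24 cholesterol synthesis genes 0 rose and 7 fell (1 and 9 adjusted over the list alone; adjusted p = 1.9e-05, and adjusted p = 0.461 with an estimated correlation). INSIG1, which regulates sterol sensing, was 3.66-fold lower (-1.87 ± 0.81). The list mean was 0.01 in SKRC10 against -1.29 to -0.45 in the other lines, -0.56 on slide A and -0.64 on slide B. Outside the list, the fatty acid desaturase gene SCD was 3.97-fold lower (-1.99 ± 0.86), the transcription factor gene SREBF1 2.98-fold (-1.58 ± 0.88), the receptor gene LRP8 3.25-fold (-1.70 ± 0.66) and the acyltransferase gene AGPAT3 3.24-fold (-1.70 ± 0.60). UGT1A6 (-1.59 ± 0.99), CDCA7 (-1.54 ± 0.29), MMAB (-1.52 ± 0.70), PIR (-1.51 ± 0.88) and the receptor kinase gene AXL (-1.47 ± 0.36) completed the 10 lowest means. Other probes had means of -0.13 and -0.64 for AGPAT3 and of -0.74 and -0.63 for MMAB. Of 61 proliferation genes 0 rose and 8 fell (0 and 8 adjusted over the list alone; adjusted p = 3.75e-07, and adjusted p = 0.627 with an estimated correlation). The mitotic kinesin gene KIF11 was 2.11-fold lower (-1.08 ± 0.49). The mean of the proliferation list was -1.33 in SKRC10 and -0.29 to -0.04 in the other lines, -0.16 on slide A and -0.79 on slide B.

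Several lower calls were lost with 3 lines, although their means stayed similar. Fry gave an adjusted p of 0.062 for the cholesterol list and of 0.204 for the proliferation list, whose call was also lost within slide A (0.0538). Calls were lost without SKRC59 for SCD, INSIG1, MMAB, PIR, SREBF1 and UGT1A6 (adjusted p 0.0577 to 0.12, means -1.84, -1.82, -1.53, -1.64, -1.42 and -1.47), without SKRC52 for SCD, PIR, SREBF1, UGT1A6 and KIF11 (0.0702 to 0.111, means -1.82, -1.20, -1.46, -1.33 and -1.04), without SKRC1 for SCD, INSIG1, MMAB, PIR, SREBF1, UGT1A6 and KIF11 (0.0508 to 0.136, means -1.87, -1.61, -1.36, -1.34, -1.41, -1.49 and -1.19) and without SKRC10 for KIF11 (0.0524, mean -0.86).

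Of the 11 genes fixed in advance that are named here, 6 were called with AZA. Whether any of them was first reported from these cell lines is also not given, so this count may not be independent evidence. NEURL1, a ubiquitin ligase gene, rose 2.09-fold (1.07 ± 0.52), besides GREM1, NEFH, LAD1, CDH1 and CDKN1A described above, while DNMT1, the maintenance DNA methyltransferase, was not called (-0.38 ± 0.39, adjusted p 0.151). The NEURL1 call was lost without SKRC59 (adjusted p 0.0866), SKRC52 (0.0857) or SKRC1 (0.0801), with means of 0.91, 0.94 and 1.13. The WNT antagonist gene SFRP1 (0.19 ± 0.15, adjusted p 0.115), the tumour suppressor genes VHL (0.53 ± 0.58, 0.101) and RASSF1 (0.10 ± 0.80, 0.863) and the hypoxia-induced CA9 (-0.11 ± 0.98, 0.866) were not called. The uridine-cytidine kinase genes UCK2 and UCK1 changed in opposite directions, by 1.27 ± 0.51 and -0.63 ± 0.16. AQP1, a water channel gene of the renal tubule, rose 5.84-fold (2.55 ± 0.39, and 1.46 by another probe), the leukocyte integrin gene ITGB2 (2.45 ± 1.05, mock signal well above background on 2 of 4 arrays) 5.47-fold and the peptide transporter gene TAP1 2.52-fold (1.33 ± 0.33).

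**Figure D1:**
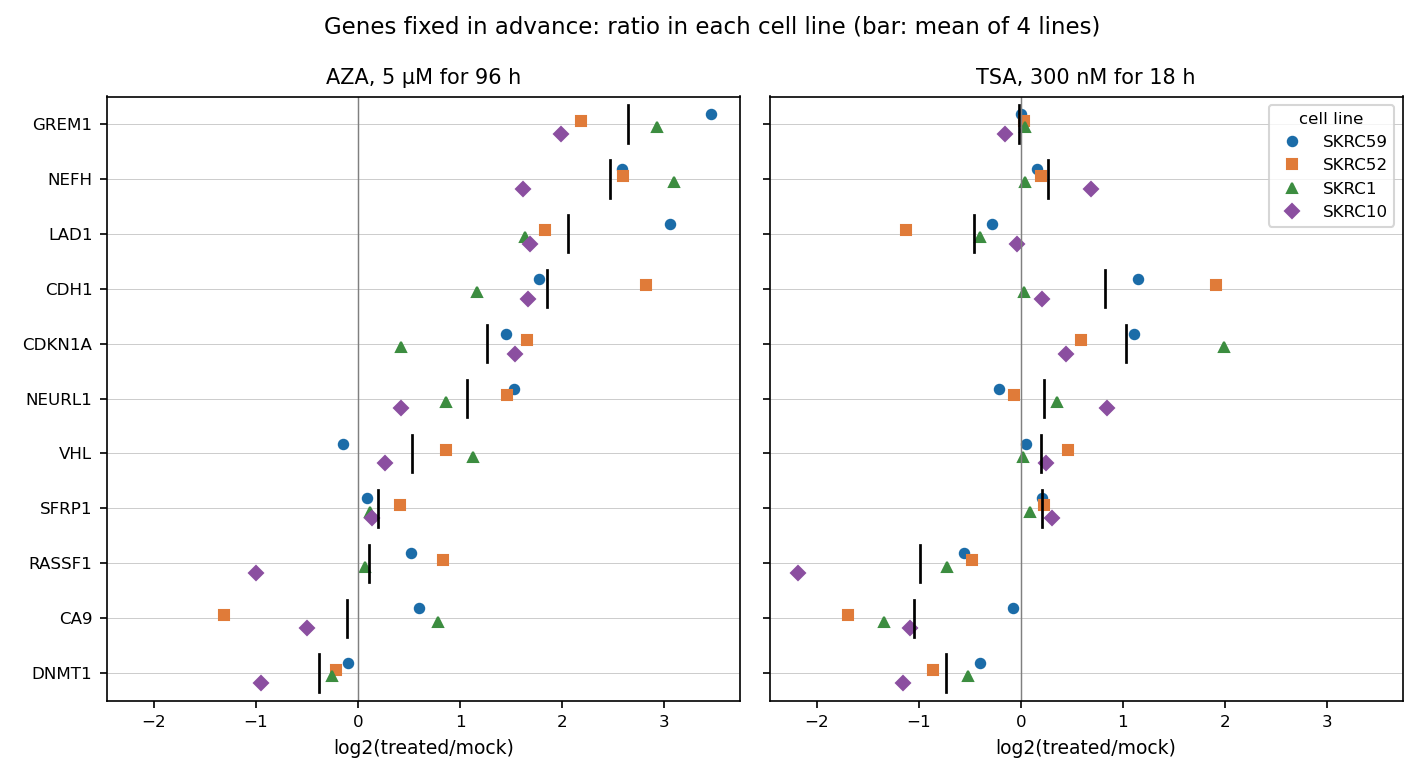
Log2 ratio of treated over mock signal (horizontal axis) of 11 genes fixed in advance, with 1 point per cell line and a bar at the mean of the 4 lines, for AZA on the left and TSA on the right. GREM1 was not well above background in any mock channel, nor in the treated channel with TSA, so its points are not exact ratios.

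The remaining 15 lists were not called with AZA, with adjusted p of 0.0569 to 0.989. The members that rose and fell numbered 3 and 0 of 25 blood and immune cell genes (3 and 0 adjusted over the list alone, as in each bracket that follows), 3 and 0 of 29 genes of MHC and antigen presentation (3 and 0), 4 and 0 of 20 WNT antagonists (4 and 0), 6 and 3 of 32 deacetylases and acetyltransferases (7 and 5), and 5 and 4 of 26 genes of endoplasmic reticulum and amino acid stress (6 and 8). They were 2 and 1 of 17 endothelial (6 and 4), 2 and 0 of 16 heat shock (2 and 0), 16 and 3 of 68 histone (17 and 3), 3 and 4 of 28 housekeeping (4 and 4), 5 and 2 of 44 hypoxia (5 and 3) and 0 and 0 of 12 metallothionein genes (0 and 0). They were 3 and 0 of 41 neuronal (1 and 0), 2 and 1 of 37 renal tubule (2 and 0), 4 and 4 of 24 DNA methylation machinery genes (4 and 5) and 0 and 2 of 25 genes reported to fall with deacetylase inhibitors (0 and 1). For DNA methylation machinery the median was -0.18, the mean 0.01 and the test direction down, and for housekeeping genes the test direction was down with a median and mean of 0.01 and 0.004.

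In all, 2680 features rose and 1880 fell with AZA (58.8% higher), and at 2-fold or more 758 rose and 133 fell (85.1% higher). With each drug given its own spread 1027 rose and 681 fell, and only 1585 of the 4560 calls were kept. All 4 lines had the same sign for 4480 of the 4560 calls (98.2%), which the test favours, since it calls genes with a small spread between these lines. Mock signal was not well above background in any line for 48 of the 758 genes raised at least 2-fold (6.3%) with AZA and for 31 of 1451 (2.1%) with TSA (Fisher's exact test, two-sided, p = 1.39e-06). Both shares lie below the 8.3% of all features with AZA and with TSA. Fisher's test takes genes as independent, so its p-value does not measure the spread between lines. The split depended on the scaling: Agilent's own ratios gave 2319 higher and 2829 lower (45% higher; 1283 and 482 at 2-fold, 72.7%), and median centring gave 1512 and 65 at 2-fold (95.9%). The counts were 717 and 472 without SKRC59, 1146 and 726 without SKRC52 and 807 and 408 without SKRC1, 2969 and 2152 with slide as a term, 194 and 47 within slide A and 23 and 0 within slide B, where limma gave 3079 and 2192 at an unadjusted p under 0.05.

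TSA changed more features than AZA did. The WNT pathway gene DACT3 rose 21.8-fold (4.44 ± 0.12), ABAT, which breaks down the transmitter GABA, 19.9-fold (4.32 ± 0.69), the protease inhibitor gene SERPINI1 (4.17 ± 0.33), ZDHHC11 15.1-fold (3.92 ± 1.17), DHRS2 13.7-fold (3.78 ± 0.20), FA2H, a fatty acid hydroxylase gene, 13.5-fold (3.76 ± 0.59) and ROPN1L 10.3-fold (3.37 ± 0.21). The matrix protein gene CCN2 (4.06 ± 1.58), ANKRD1 (3.65 ± 1.31) and the growth factor gene AREG (3.25 ± 1.44) rose less evenly: CCN2 and ANKRD1 had means of 4.64 and 4.30 without SKRC10, and AREG had 3.93 without SKRC52. The methyltransferase gene NNMT (-3.81 ± 0.26), AMIGO2 13.1-fold lower (-3.71 ± 0.41), NMI (-3.58 ± 0.68), the plasminogen activator gene PLAU (-3.46 ± 0.12), RIN2 (-3.46 ± 0.46), RBMS3 10.2-fold lower (-3.35 ± 1.16), the deacetylase gene HDAC7 9.85-fold lower (-3.30 ± 0.24), NEXN (-3.08 ± 1.12), EVA1A (-3.07 ± 0.44) and UGT2B7 (-3.04 ± 0.32) had the lowest means. Other probes had lower means for DACT3 (0.23) and ABAT (1.67) and a higher one for DHRS2 (4.93), so the DACT3 change rests on a single probe. They had -1.76 and -1.25 for RIN2, -1.17 and -1.60 for RBMS3, -2.52 for HDAC7 and -2.09 for NEXN. The adjusted p of these 20 genes was 1.06e-05 to 0.00563. Mock signal was well above background on 2 of 4 arrays for SERPINI1 and FA2H.

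The metallothionein, histone, neuronal, ribosomal and deacetylase inhibitor response lists were higher with TSA. Of 12 metallothionein genes, which encode metal-binding proteins, 10 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 4.9e-07, and adjusted p = 0.269 with an estimated correlation). MT1X rose 2.4-fold (1.26 ± 0.17), MT1H 2.37-fold (1.25 ± 0.17) and MT1A 2.04-fold (1.03 ± 0.12). Metallothioneins are closely related in sequence, so their probes cannot be assigned to single genes. Of 68 histone genes 36 rose and 2 fell (42 and 2 adjusted over the list alone; adjusted p = 8.07e-07, and adjusted p = 0.517 with an estimated correlation). H2AC18 (2.12 ± 0.54), the linker histone gene H1-10 (1.12 ± 0.35) and H3-3A (0.70 ± 0.19) rose, with a mean of 0.70 for another H2AC18 probe. Of 41 neuronal genes 15 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 2e-04, and adjusted p = 0.082 with an estimated correlation). The tubulin gene TUBB3 (1.56 ± 0.50), the vesicle gene RAB3A (1.14 ± 0.22), VGF (1.08 ± 0.42) and the granin gene CHGB (1.77 ± 0.73, mock signal well above background on 1 of 4 arrays) were among them. Another probe had a mean of 0.47 for TUBB3 and of 1.09 for CHGB. Of 32 genes reported to rise with deacetylase inhibitors 20 rose and 3 fell (25 and 3 adjusted over the list alone; adjusted p = 7.14e-06, and adjusted p = 0.133 with an estimated correlation). SAT1 rose 3.76-fold (1.91 ± 0.48) and the glutaredoxin gene GLRX 2.83-fold. This deacetylase inhibitor list shares 4 genes with the histone list, 2 with the metallothionein list and 2 with the neuronal list. Of 63 ribosomal protein genes 28 rose and 4 fell (31 and 6 adjusted over the list alone; adjusted p = 0.00217, and adjusted p = 0.376 with an estimated correlation). This ribosomal call was lost with Agilent's own ratios (adjusted p 0.409). The means on slides A and B were 1.23 and 1.01 for metallothionein, 0.72 and 0.64 for histone, 0.54 and 0.39 for neuronal, 1.11 and 1.13 for deacetylase inhibitor and 0.23 and 0.18 for ribosomal genes.

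The proliferation, interferon, DNA methylation, cytokine and deacetylase inhibitor response lists were lower with TSA. Of 61 proliferation genes 2 rose and 34 fell (2 and 35 adjusted over the list alone; adjusted p = 4.9e-07, and adjusted p = 0.714 with an estimated correlation). The thymidylate synthase gene TYMS was 5.81-fold lower (-2.54 ± 0.73), the mitotic kinase gene AURKA 2.95-fold (-1.56 ± 0.37), the cell cycle regulator FOXM1 2.83-fold and the ribonucleotide reductase gene RRM1 2.15-fold (-1.11 ± 0.41). The proliferation list mean was 0.02 in SKRC59 and -1.19 to -0.57 in the other lines. Of 25 genes reported to fall with deacetylase inhibitors 0 rose and 12 fell (0 and 12 adjusted over the list alone; adjusted p = 6.24e-05, and adjusted p = 0.382 with an estimated correlation). HMGA2 was 8.15-fold lower (-3.03 ± 0.95) and the cyclin gene CCND1 6.93-fold (-2.79 ± 0.53). The other probe of HMGA2 had a mean of -0.22, so that change rests on a single probe, and other CCND1 probes had -2.01 and -2.30. This deacetylase inhibitor list shares 6 genes with the proliferation list and 2 with the DNA methylation machinery list. Of 56 interferon-stimulated genes 5 rose and 24 fell (7 and 25 adjusted over the list alone; adjusted p = 6.24e-05, and adjusted p = 0.588 with an estimated correlation). IFIT3 (-2.92 ± 0.71, treated signal well above background on 2 of 4 arrays), PARP14 (-2.40 ± 0.62, on 3 of 4), SAMD9L (-2.36 ± 0.39) and XAF1 (-1.83 ± 0.48) fell, with -1.62, -0.52 and -1.27 for other PARP14 probes. Of 24 DNA methylation machinery genes 1 rose and 11 fell (1 and 12 adjusted over the list alone; adjusted p = 0.000298, and adjusted p = 0.133 with an estimated correlation). DNMT1 fell by 0.73 ± 0.34, the methyl-CpG binding protein genes MBD3 by 0.95 ± 0.07 and MBD2 by 0.50 ± 0.07, and UCK1 by 0.58 ± 0.10 on the log2 scale. Another probe had a mean of -0.65 for MBD3 and of -0.06 for MBD2, so the MBD2 change rests on a single probe. Of 36 cytokine genes 1 rose and 9 fell (1 and 8 adjusted over the list alone; adjusted p = 0.0125, and adjusted p = 0.714 with an estimated correlation). IL6 (-3.03 ± 1.15), CXCL2 (-2.57 ± 1.09) and LIF (-1.92 ± 0.20) fell, and SOD2, which encodes a mitochondrial antioxidant enzyme, rose (1.23 ± 0.16). Another probe had a mean of -1.19 for CXCL2 and of -0.52 for LIF. The means on slides A and B were -0.58 and -0.88 for proliferation, -0.80 and -0.99 for deacetylase inhibitor, -0.62 and -0.41 for interferon, -0.48 and -0.56 for methylation machinery and -0.34 and -0.88 for cytokine genes.

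The proliferation call had an adjusted p of 0.0758 with fry, and the cytokine call was lost with fry (0.0561), within slide A (0.175) and without SKRC10 (0.0698), while DNMT1 lost its call without SKRC52 (0.0613, mean -0.69).

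Single members of lists that were not called changed strongly with TSA. The p53 targets FAS (-1.69 ± 0.79), PHLDA3 (-1.90 ± 0.28) and the cell death gene BAX (-1.28 ± 0.21) fell, CDKN1A rose 2.04-fold (1.03 ± 0.70), and the CDKN1A call was lost without SKRC59 (adjusted p 0.111, mean 1.01). Of the renal tubule list, the injury marker HAVCR1 was 6.05-fold (-2.60 ± 0.52), the scaffold gene PDZK1 7.09-fold (-2.83 ± 0.89) and the kidney transcription factor gene PAX8 5.16-fold (-2.37 ± 1.11) lower. HDAC3 rose 2.43-fold (1.28 ± 0.13) and the acetyltransferase gene CREBBP was 1.95-fold lower (-0.96 ± 0.13). The chaperone genes HSPA1A (2.03 ± 0.97) and HSP90AA1 (1.86 ± 0.48), the antigen presentation gene HLA-DMB (2.70 ± 0.69) and the germline gene TDRKH (1.46 ± 0.29) rose, and the immunoproteasome gene PSMB8 fell (-2.04 ± 0.38). Other probes had means of -0.04 and -1.17 for BAX, of 1.39 and 1.21 for HSPA1A, of -1.17 for PAX8 and of 1.58 for CDKN1A. Of the genes fixed in advance, RASSF1 (-0.98 ± 0.80) had an adjusted p of 0.0633, and of 0.0407 with cell line as a block, 0.0218 with slide as a term and 0.0347 without SKRC10 (mean -0.59). With slide as a term CDH1 had 0.02, and without SKRC59 CA9 had 0.0482 (mean -1.37). CDH1 (0.83 ± 0.87, adjusted p 0.104), CA9 (-1.05 ± 0.69, 0.0626), LAD1 (-0.46 ± 0.47, 0.209), NEFH (0.27 ± 0.29, 0.378), NEURL1 (0.23 ± 0.48, 0.475), SFRP1 (0.21 ± 0.09, 0.0629) and VHL (0.19 ± 0.21, 0.491) were not called, and GREM1 was not well above background in either channel. Mock signal was well above background on 2 of 4 TSA arrays for CDH1 and NEFH and on 1 of 4 for LAD1.

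The remaining 17 lists were not called with TSA, with adjusted p of 0.109 to 0.99. The members that rose and fell numbered 6 and 2 of 87 cancer-testis genes (2 and 1 adjusted over the list alone, as in each bracket that follows), 7 and 5 of 32 p53 targets (8 and 5), 3 and 5 of 30 epithelial (3 and 4), 1 and 3 of 27 mesenchymal (1 and 3), 5 and 5 of 34 imprinted (5 and 5) and 5 and 4 of 64 hypermethylated genes (4 and 3). They were 3 and 3 of 24 cholesterol synthesis (2 and 3), 7 and 0 of 25 blood and immune cell (5 and 0), 3 and 7 of 29 MHC (3 and 7), 2 and 0 of 20 WNT antagonist (2 and 0), 7 and 10 of 32 deacetylase and acetyltransferase (7 and 11) and 7 and 7 of 26 endoplasmic reticulum and amino acid stress genes (10 and 8). They were 1 and 1 of 17 endothelial (1 and 1), 3 and 3 of 16 heat shock (3 and 3), 5 and 7 of 28 housekeeping (7 and 7), 13 and 4 of 44 hypoxia (15 and 7) and 4 and 7 of 37 renal tubule genes (4 and 7). The test direction was down although the median and mean were above 0 for the cholesterol synthesis, imprinted and housekeeping lists. Median and mean differed in sign for the deacetylase, endoplasmic reticulum stress and heat shock lists.

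In all, 4834 features rose and 4359 fell with TSA, 1451 and 1244 of them at least 2-fold (53.8% higher), and 8958 of the 9193 calls (97.4%) had the same sign in all 4 lines. Median centring gave 2689 and 767 at 2-fold (77.8% higher). The counts were 3187 and 2995 without SKRC59, 5033 and 4711 with slide as a term, 2140 and 1809 within slide A and 1424 and 1525 within slide B.

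**Figure D2:**
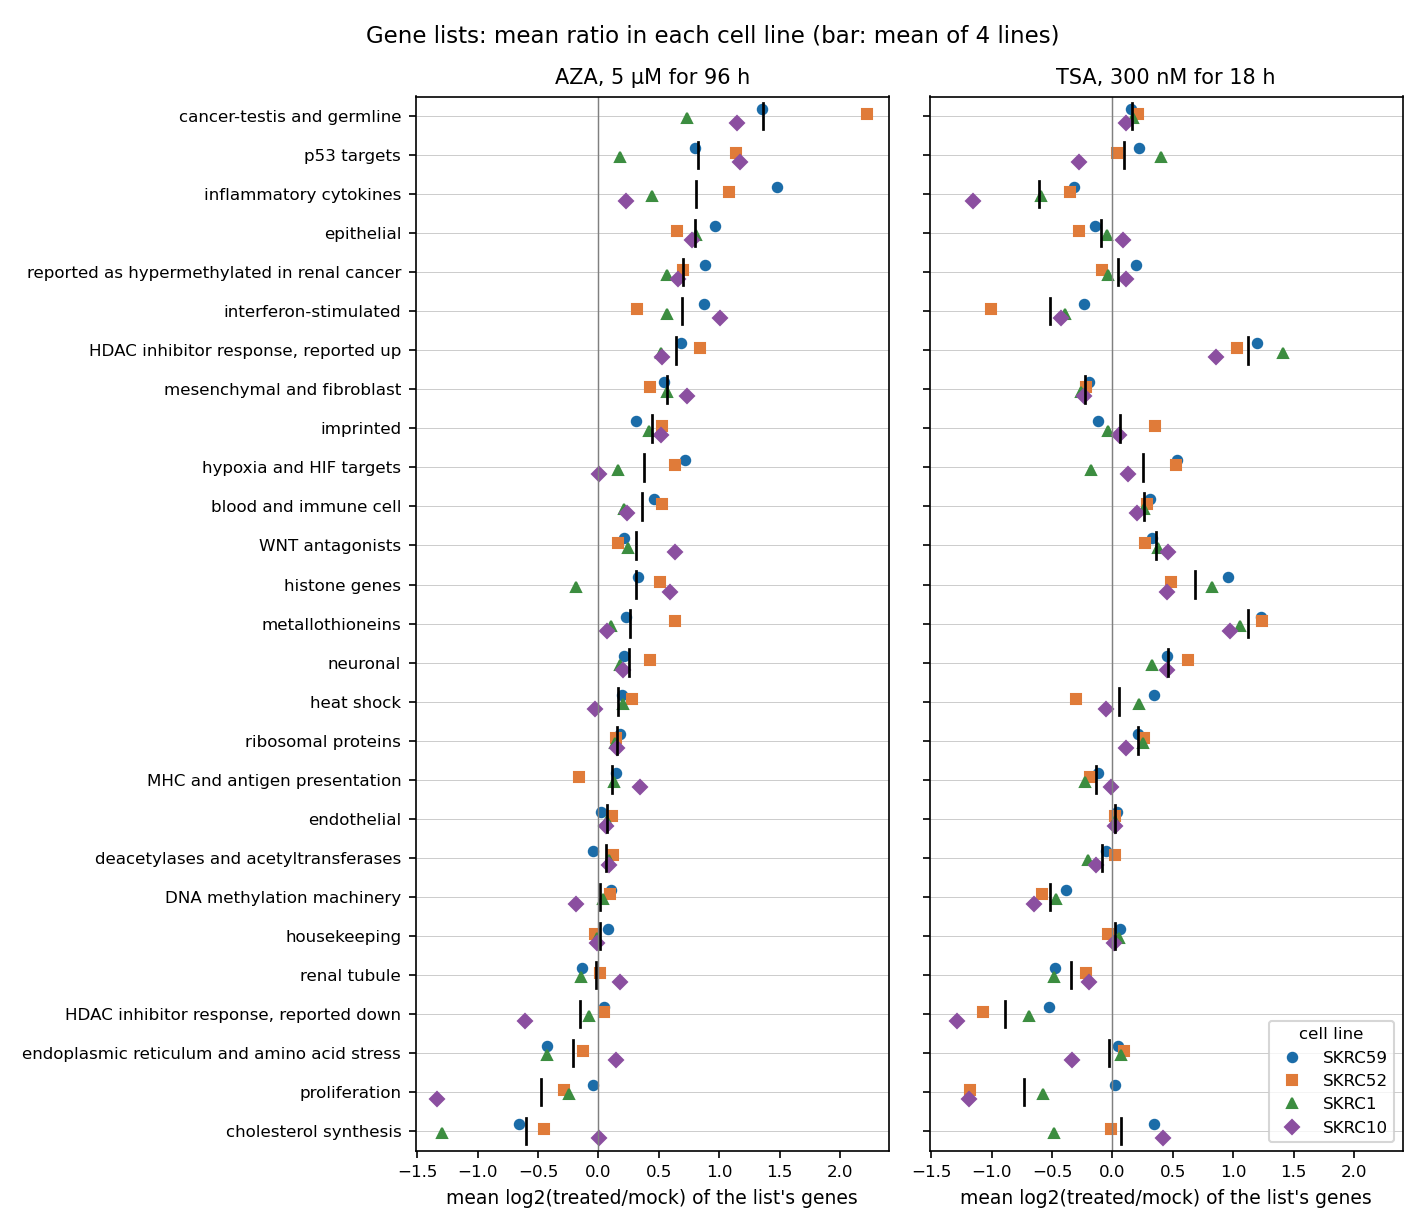
Mean log2 ratio of treated over mock signal (horizontal axis) of each of the 27 gene lists, with 1 point per cell line and a bar at the mean of the 4 lines, for AZA on the left and TSA on the right. The interferon list lies between 0.32 and 1.01 with AZA and between -1.01 and -0.24 with TSA, and the proliferation list reaches -1.33 with AZA in SKRC10.

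The third comparison, AZA minus TSA, asked where the responses to the drugs differed. The interferon-stimulated list had the smallest p of the 27 lists: 28 of 56 genes had a higher ratio with AZA and 0 a lower one (34 and 0 adjusted over the list alone; adjusted p = 2.87e-12, and adjusted p = 0.22 with an estimated correlation). The mean difference of the list was 1.21, below the 1.41 of the cytokine list, and it was 1.22 on slide A and 1.20 on slide B. SAMD9L differed by 2.64 on the log2 scale, XAF1 by 2.39, IFIH1 by 2.28 and IRF9 by 1.71. The largest single differences were higher with AZA for IL6 (4.67), FMR1NB (4.36), PAGE5 (4.27), PLAC8 (4.16) and GCNA (4.11), and higher with TSA for DACT3 (-3.47), ACADSB (-3.35), SERPINI1 (-3.34), EAF2 (-3.17) and ABAT (-3.14), with adjusted p of 0.000246 to 0.0164. Another DACT3 probe had means of -0.04 with AZA and 0.23 with TSA, and another ABAT probe 0.23 and 1.67. The IL6 call was lost without SKRC59 (adjusted p 0.0568, difference 4.39), and the PLAC8 call without SKRC59 (0.0951, 4.15) or SKRC10 (0.0749, 4.16).

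A further 10 lists had higher ratios for AZA. Members with a higher and lower ratio numbered 21 and 1 of 87 cancer-testis genes (24 and 1 adjusted over the list alone; adjusted p = 8.15e-09, and adjusted p = 0.445 with an estimated correlation). SYCP3 differed by 3.81, XAGE3 by 3.91 and MAEL by 3.19. Members numbered 9 and 0 of 36 cytokine genes (14 and 0 adjusted over the list alone; adjusted p = 2.36e-07, and adjusted p = 0.266 with an estimated correlation), with LIF at 1.80 (another probe had means of -0.12 with AZA and -0.52 with TSA). They were 9 and 0 of 27 mesenchymal genes (12 and 1 adjusted over the list alone; adjusted p = 0.000252, and adjusted p = 0.103 with an estimated correlation). Of 30 epithelial genes 5 were higher and 2 lower (15 and 2 adjusted over the list alone; adjusted p = 0.000807, and adjusted p = 0.11 with an estimated correlation). KRT7 differed by 3.68 and LAD1 by 2.51. Of 32 p53 targets 7 were higher and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 0.00115, and adjusted p = 0.561 with an estimated correlation), with FAS at 3.56 and PHLDA3 at 2.40. They were 4 and 0 of 24 DNA methylation machinery genes (5 and 0 adjusted over the list alone; adjusted p = 0.00144, and adjusted p = 0.11 with an estimated correlation), with UCK2 at 2.42. Of 25 genes reported to fall with deacetylase inhibitors 7 were higher and 0 lower (7 and 0 adjusted over the list alone; adjusted p = 0.00207, and adjusted p = 0.445 with an estimated correlation), with CCND1 at 2.59. Of 34 imprinted genes 7 were higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.00575, and adjusted p = 0.371 with an estimated correlation). For 64 hypermethylated genes they were 8 and 3 (11 and 4 adjusted over the list alone; adjusted p = 0.00575, and adjusted p = 0.205 with an estimated correlation), with CST6 at 3.54 and NEFH at 2.20. For 29 MHC genes they were 7 and 3 (8 and 4 adjusted over the list alone; adjusted p = 0.0419, and adjusted p = 0.561 with an estimated correlation), with TAP1 at 2.26. The mean differences on slides A and B were 1.61 and 0.80 for cancer-testis, 1.61 and 1.21 for cytokine, 0.69 and 0.90 for mesenchymal, 1.01 and 0.77 for epithelial and 0.84 and 0.61 for p53 genes, where SKRC1 went the other way (-0.23). They were 0.58 and 0.48 for methylation machinery, 0.84 and 0.64 for deacetylase inhibitor, 0.30 and 0.46 for imprinted, 0.74 and 0.57 for hypermethylated and 0.15 and 0.35 for MHC genes. The p53 call was lost with fry (adjusted p 0.104) and without SKRC10 (0.0697), and the MHC call with fry (0.0521), within slide A (0.138) and without SKRC59 (0.0777) or SKRC1 (0.0844).

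Lists with a higher ratio for TSA were metallothioneins, with 0 higher and 8 lower of 12 for AZA minus TSA (0 and 8 adjusted over the list alone; adjusted p = 1.01e-06, and adjusted p = 0.211 with an estimated correlation), such as MT1X (-1.26) and MT1A (-0.97). Of 68 histone genes 0 were higher and 6 lower (0 and 4 adjusted over the list alone; adjusted p = 0.000865, and adjusted p = 0.561 with an estimated correlation). Cholesterol synthesis genes followed, with 0 and 6 of 24 (0 and 6 adjusted over the list alone; adjusted p = 0.00354, and adjusted p = 0.612 with an estimated correlation), including INSIG1 (-2.27). Of 41 neuronal genes 1 was higher and 6 lower (1 and 8 adjusted over the list alone; adjusted p = 0.00984, and adjusted p = 0.11 with an estimated correlation). Of 32 genes reported to rise with deacetylase inhibitors 1 was higher and 5 lower (3 and 6 adjusted over the list alone; adjusted p = 0.0128, and adjusted p = 0.334 with an estimated correlation). The mean differences on slides A and B were -0.80 and -0.93 for metallothionein, -0.30 and -0.44 for histone, -0.72 and -0.61 for cholesterol, -0.22 and -0.20 for neuronal and -0.35 and -0.61 for deacetylase inhibitor genes. The histone difference rests on SKRC59 (-0.63) and SKRC1 (-1.02), with 0.02 in SKRC52 and 0.14 in SKRC10. HDAC3 (-1.58) and HDAC7 (3.23) differed in opposite directions. The histone and cholesterol calls were lost with fry (adjusted p 0.137 and 0.161), the histone and deacetylase inhibitor calls without SKRC1 (0.0736 and 0.143), and the INSIG1 call without SKRC59 (0.0858) or SKRC1 (0.0566), with a difference of -2.11 each time.

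Of the genes fixed in advance, CDH1 (1.03, adjusted p 0.198) and RASSF1 (1.09, 0.18) had an adjusted p of 0.0114 and 0.00514 with cell line as a block. Without SKRC10, NEURL1 had 0.0271 (difference 1.26) and RASSF1 0.0305 (1.06). CDKN1A (0.23, adjusted p 0.75), CA9 (0.94, 0.272), DNMT1 (0.35, 0.36), NEURL1 (0.84, 0.11), SFRP1 (-0.02, 0.934) and VHL (0.33, 0.466) were not called. The remaining 11 lists were not called, with adjusted p of 0.111 to 0.961. Members higher and lower numbered 3 and 0 of 61 proliferation genes (1 and 0 adjusted over the list alone, as in each bracket that follows), 2 and 2 of 25 blood and immune cell (2 and 2), 0 and 2 of 20 WNT antagonist (0 and 2), 7 and 5 of 32 deacetylase and acetyltransferase (8 and 6), 3 and 5 of 26 endoplasmic reticulum and amino acid stress (4 and 6) and 1 and 1 of 17 endothelial genes (1 and 1). They were 2 and 3 of 16 heat shock (5 and 4), 1 and 0 of 28 housekeeping (0 and 0), 6 and 4 of 44 hypoxia (6 and 4), 2 and 0 of 37 renal tubule (1 and 0) and 1 and 1 of 63 ribosomal protein genes (0 and 0). The proliferation list had an adjusted p of 0.0429 with cell line as a block, of 0.0119 without SKRC59 and of 0.0048 without SKRC10, and the blood and immune cell list had a median of -0.03 and a mean of 0.09.

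In all, 2501 features had a higher and 2196 a lower ratio with AZA than with TSA, 1300 and 930 of them by at least 2-fold. The counts were 1051 and 866 without SKRC59, 1687 and 1253 without SKRC52, 1130 and 1063 without SKRC1 and 1812 and 1426 without SKRC10. They were 2731 and 2327 with slide as a term, 39 and 15 within slide A and 0 and 0 within slide B, where limma gave 3199 and 2387 at an unadjusted p under 0.05. Agilent's own ratios gave 2284 and 2664 and median centring 2518 and 2730, so the majority depended on the scaling.

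Features raised with AZA alone from signal near background were counted for the question in the series title. Each line held 140 to 167 features that were at least 2-fold higher with AZA, under 1.4-fold higher with TSA and not well above background in mock cells, and 116 met this in at least 2 lines, 38 in at least 3 and 11 in all 4. Mock signal near background is shared by the lines, so candidates were permuted 1000 times among features near background in the same lines, a test chosen after seeing the data. This gave a mean of 17.91 in at least 2 lines, with a highest value of 29. The 11 included GREM1 and, chosen after their values were seen, the germline genes DAZL, DDX43 and STRA8. GREM1 may not be independent evidence here either, as stated above for the genes fixed in advance. The 116 held 8 of 87 cancer-testis genes, 3 of 34 imprinted genes and 3 of 64 hypermethylated genes. With Agilent's own ratios 384 features met the criteria in at least 2 lines and 28 in all 4, which held 5 of the 11, and GREM1 met them in 4 lines under each threshold tried.

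The responses to the drugs overlapped in part. Across genes, which are not independent replicates, mean ratios with AZA and TSA had a Pearson correlation of 0.301 and a Spearman correlation of 0.33. Pairs of single arrays had a mean Pearson correlation of 0.315 within a line and of 0.182 between different lines. Both drugs raised 912 features, against 454.2 for independent lists, and both lowered 941, against 287.3, while 209 rose with AZA and fell with TSA, against 409.6, and 129 did the reverse, against 318.6. Between lines, log2 ratios correlated at 0.46 to 0.636 with AZA and at 0.66 to 0.765 with TSA. Lines on the same slide had means of 0.553 and 0.72 and lines on different slides 0.529 and 0.701.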

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

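The tests of other probes, of the slide and of the cell line for genes called alike with both drugs, and the slide test for cholesterol synthesis, were chosen only after the result was seen. A line far from the other 3 was found for 13 of 192 values tested with Dixon's criterion (6.8%), where chance gives about 1 in 20, so the list may hold chance results; the nearest pattern weighed below is cholesterol synthesis in SKRC10 (mean residual 0.426). With AZA, SKRC10 stood apart for SCD (-0.70, others -2.49 to -2.34) and SREBF1 (-0.27, others -2.08 to -1.91). SKRC1 stood apart for CDKN1A (0.42, others 1.45 to 1.66), SKRC59 for LAD1 (3.06, others 1.64 to 1.83) and AQP1 (3.12, others 2.32 to 2.39), and SKRC52 for CST6 (3.08, others 3.79 to 3.87) and SFRP1 (0.41, others 0.09 to 0.14). The mean of the housekeeping list was 0.078 in SKRC59 and -0.03 to -0.01 in the others, and that of the neuronal list 0.42 in SKRC52 and 0.17 to 0.21 in the others. With TSA, SKRC10 stood apart for ANKRD1 (1.68, others 4.22 to 4.40), RASSF1 (-2.18, others -0.72 to -0.48) and the mean of the endoplasmic reticulum stress list (-0.34, others 0.05 to 0.10), and SKRC59 for the endothelial list (0.038, others 0.019 to 0.021).

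The AZA ratio differed between the lines of slide A and those of slide B for 2 of 28484 features by limma's test of that difference, and the TSA ratio for 0, with 2013 and 1897 features at an unadjusted p under 0.05. They were UQCRH, chosen after its values were seen, and a feature without a current symbol, both with higher ratios in SKRC1 and SKRC10.

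The first pattern weighed is the 1853 features called in the same direction with both drugs. A dye effect of single probes would leave the other probes of a gene near chance, but 85.6% (507 of 592 genes with several probes) had the called sign with both drugs, where a dye effect that is alike with both drugs would give 50%. A slide effect would bring lines of one slide closer together, but correlations between AZA and TSA ratios of different lines were only 0.016 higher on a shared slide. Deviations of a line from the drug means were shared between the drugs, with a mean correlation of 0.363 and a lowest of 0.278, so part of the overlap may come from the line and its culture. A dye effect common to all probes of a gene, and a general response to either treatment, stay open and were not tested.

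The second pattern is that AZA calls of at least 2-fold were mostly higher (85.1%). Among genes well above background in both channels on all arrays the share was 77.5%, which argues against the floor of the background as the whole cause. Under 6 other signal treatments it was at least 72.7%, which argues against the normalization for calls of this size, although over calls of any size Agilent's ratios gave 45% higher. A constant dye effect alone would give the raised genes a similar ratio with TSA. Of these genes 62.8% (476 of 758) had a TSA ratio under 1.4-fold, which argues against it as their whole cause. The share among all genes was higher, at 85%, so the raised genes more often reached 1.4-fold with TSA. A dye effect as part of the cause stays open. Of the raised genes, 6.3% were not well above background in mock cells of any line, against 8.3% of all features, so most were not silent in every line. Loss of DNA methylation is a candidate explanation that these arrays cannot test, since no methylation was measured and time and drug are confounded.

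The third pattern is that cholesterol synthesis genes were not lowered in SKRC10 with AZA (list mean 0.01, against -0.66, -0.45 and -1.29 in SKRC59, SKRC52 and SKRC1). The mean residual from the line through all genes was 0.426 in SKRC10, above the -0.157 to 0.173 of random lists. Such lists do not hold the spread of genes regulated together: the residual was -1.025 in SKRC1, which departed most, -0.153 in SKRC59 and 0.163 in SKRC52. The slope of SKRC10 on the other lines was 0.564. Scaled by it, the list means of the other lines would be -0.729 to -0.255, against 0.006 in SKRC10. Any positive slope leaves a negative mean negative, so this cannot decide whether a smaller response of the SKRC10 array explains the pattern. The proliferation list also changed more in SKRC10 (-1.33) than in the other lines (-0.29 to -0.04). The SKRC10 array thus did not respond less in every list, but a smaller response to AZA as part of the cholesterol pattern stays open. The slide alone does not account for the pattern, since SKRC1 on the same slide had the lowest mean, -1.293. With TSA the list mean was also highest in SKRC10 (0.42) and lowest in SKRC1 (-0.486), with 0.347 in SKRC59 and -0.008 in SKRC52. The place of these lines in the order was therefore not particular to AZA. A difference between the lines or between single cultures may lie behind the AZA pattern, and 1 array per line and drug does not separate these.

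As a check on chance, 1 of the 8 sign patterns of the 4 arrays, the real one, gave as many calls with AZA (4560, highest other 0) and with TSA (9193, highest other 0), which are too few patterns for a share under 0.05. For AZA minus TSA, the arrays are paired by line, and 1 of the 8 splits that part both arrays of every line, the real one, gave as many calls (4697, highest other 0), again too few for a share under 0.05. The remaining 27 of the 35 splits keep both arrays of at least 1 line together; the highest of them gave 1, and the split by slide gave 0.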

How the results depend on the processing

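The slide and leave-one-line-out alternatives for the gene lists were chosen after seeing the data. No named gene or called list reversed under the alternatives run. Among all calls, median centring called 6 with AZA and 16 with TSA in the opposite direction, and averaging probes 2 and 4, and 1 for AZA minus TSA. Of the genes called and named in the text, 55 with AZA, 64 with TSA and 32 for AZA minus TSA, every one was called under each other background correction, scaling, unfiltered test, every-probe test, variance prior, array weighting, slide term and the value table, except 1 with AZA and 1 with TSA under median centring. Averaging probes lost 1 with AZA, requiring signal above background in both channels of all arrays lost 1 of the 36 AZA genes that pass, and giving each drug its own spread lost 9 with AZA. Of the named genes not called, median centring called 1 of 5 with AZA and 4 of 9 with TSA, and averaging probes 1 and 1. With TSA, slide as a term called 2 of 9, and Agilent's ratios, each drug's own spread and array weights 1 each, as did the filter on both channels (1 of 5). For AZA minus TSA, Agilent's ratios called 1 of 8 and leaving out SKRC10 2. Within slide A 23, 50 and 9 were still called, and within slide B 5, 46 and 0, where only 2 arrays per drug enter. Aquantile after loess leaves the ratios unchanged by construction.

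Main counts of higher and lower features were 2680 and 1880 with AZA, 4834 and 4359 with TSA and 2501 and 2196 for AZA minus TSA. Median centring gave 6966 and 5349 with AZA and 8639 higher with TSA, Agilent's ratios 2319 and 2829 with AZA, where the majority turned, and each drug's own spread 1027 and 681 with AZA; the cause was not tested. For AZA minus TSA the majority also turned, with 2284 and 2664 under Agilent's ratios and 2518 and 2730 under median centring; the cause was not tested. Within slide A the counts were 194 and 47, 2140 and 1809, and 39 and 15, and within slide B 23 and 0, 1424 and 1525, and 0 and 0, with fewer samples. At 2-fold or more they were 758 and 133, 1451 and 1244, and 1300 and 930, a stricter criterion by construction. Leaving out 1 line gave 717 to 2188 higher and 408 to 1759 lower with AZA, 3187 to 3675 and 2995 to 3511 with TSA, and 1051 to 1812 and 866 to 1426 for AZA minus TSA. With cell line as a replicate block the counts were 2605 and 1879, 4775 and 4426, and 3482 and 2889, and beyond the calls of RASSF1, CDH1 and the proliferation list given above, the pairing by line changed no other call of a named gene or list.

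Camera called 12 lists with AZA, 10 with TSA and 16 for AZA minus TSA, and 0, 0 and 0 with an estimated correlation. With that estimate, 4, 4 and 6 of the called lists had an unadjusted p under 0.05. The repeat changed only the correlation setting. All camera calls of lists, and their small adjusted p-values, therefore depend on the preset correlation of 0.01. Fry kept 10, 8 and 12. No called list changed the sign of its mean under another scaling. Leaving out 1 line kept 12, at least 9 and at least 13 of these calls. The 116 features with AZA alone in at least 2 lines became 359 at 1.4-fold, 763 without the mock condition and 384 with Agilent's ratios, and 70 to 84 without 1 line, and the 11 in all lines became 29, 91 and 28; wider criteria admit more by construction, and the cause was not tested for Agilent's ratios. The correlation between the drugs was 0.301 for means of 4 lines. Pairs of single arrays had a mean of 0.315 within a line and of 0.182 between different lines, which leaves out the shared line. Means of 2 lines with no line shared gave 0.226. Signal over background limits low genes: 8.3% of features were not well above background in the mock channel of any AZA array.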

Other observations

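More zinc finger genes rose with AZA than independent calls would give, although most were not called. Families of symbols were tested after the data were seen, 233 of them with at least 10 members. Of 430 measured genes named ZNF 135 rose (50.4 expected, hypergeometric test, adjusted p 5.24e-26) and 13 fell. Among ZNF genes that the reference table places on chromosome 19, 90 of 202 rose (44.6%) and 3 fell, against 45 and 10 of 228 elsewhere (19.7% rose; Fisher's exact test, two-sided, odds ratio 3.26, p = 4.63e-08) and 11.8% of other symbols on that chromosome. The split by chromosome was also chosen after the data were seen. Both tests take genes as independent, so their p-values do not measure the spread between lines. Where a ZNF gene called higher with AZA had several probes, the others were higher too for 47 of 49. ZNF404 (2.35 ± 0.86, n = 4 lines), ZNF542P (2.15 ± 0.90) and ZNF165 (1.52 ± 0.43) had the highest means. The direction of the family mean was the same under every scaling tried. On chromosome 19, 44 of 202 ZNF genes rose and 9 fell with TSA, against 31 and 51 of 228 elsewhere.

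With TSA, 7 of 10 HOXB genes, which pattern the body axis, fell (adjusted p 0.0216), including HOXB2 (-2.40), HOXB6 (-2.29) and HOXB9 (-2.22). Of 18 IFT genes, which serve transport in cilia, 14 rose (adjusted p 4.83e-05), with the highest mean for IFT88 (1.48). Of 12 SRSF genes of splicing factors 8 fell (adjusted p 0.0189), including SRSF8 (-1.39), SRSF1 (-1.33) and SRSF4 (-1.33). These family means kept their direction with TSA under every scaling tried.

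UQCRH, a gene of mitochondrial complex III, had an AZA log2 ratio of 4.94 in SKRC1 and 5.42 in SKRC10, against 0.56 in SKRC59 and 0.36 in SKRC52 (adjusted p 0.0243 for the difference between these pairs of lines, which also differ in slide). Its mock log2 signal was 7.8 and 7.5 in SKRC1 and SKRC10 and 14.7 and 15.2 in SKRC59 and SKRC52, and a second probe gave similar ratios.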
